A study of Bos taurus with 6 samples.

How the data were processed

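Circular RNAs (circRNAs), covalently closed RNAs formed when a downstream splice site joins an upstream one, were sequenced in subcutaneous fat of 6 Qinchuan cattle. The libraries came from 3 calves of 6 months and 3 adults of 24 months. Per the labels' protocols, ribosomal RNA was removed, an incubation with RNase R, an exonuclease that digests linear RNA, is described, and the second cDNA strand was removed before paired-end sequencing on an Illumina instrument. The submitters' processing notes name Trim Galore, TopHat2 2.0.14, TopHat and Cufflinks. The program that called the circRNAs and the genome build are not given in the sources used here.

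Per the file headers, the authors deposited a back-splice junction read count for each of 14274 circRNAs in each of the 6 libraries. A count of 1 occurred 0 times in the table and the smallest nonzero count was 2, so circRNAs under 2 reads in a library stand at 0; how single reads were handled is not given. The same table holds a column headed TPM. As deposited by the authors, its values were CPM (counts per 1e6), junction reads scaled to the library total of junction reads without a length term, differing from CPM recomputed from the counts by a share of at most 4.8e-15. A deposited annotation table gives each circRNA's chromosome, start, end, strand, class, annotated genes and lengths. End minus start equalled the given full length in all 14274 entries. Whether starts count from 0 or 1 is not given, so coordinates are printed as the authors' files give them. The annotation table also lists junction reads, identical to the count table for all 14274 circRNAs, and reads under the header non-junction read for each library that detected the circRNA. How a non-junction read was defined is not given in the sources used here. The labels' protocols describe RNase R and then name rRNA-depleted or circRNA samples, so whether these 6 libraries were treated is not certain. If they were, non-junction reads are not a direct measure of the linear transcript, and the ratio results carry that doubt.

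The authors' deposited comparison of the ages holds, per the file headers, group means of scaled junction reads (a normalised signal), their log2 fold change, and a raw and adjusted p-value for each listed circRNA. The program behind it is not given in the sources used here. The authors' deposited enrichment tables hold raw and corrected p-values for gene ontology and KEGG terms of the host genes. All 6 libraries were assigned to their age, and 0 columns of per-sample values were left unassigned. Of 4790 annotated gene identifiers, 4564 were named by the deposited annotation and 226 had no symbol there. A RefSeq gene table of the assembly ARS-UCD2.0 was used only to bring older symbols to current ones, which matched 221 identifiers; none of its coordinates were used.

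Junction reads were compared between ages with the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3. TMM scaling (factors 0.9641 to 1.03) and the filterByExpr filter with age as the group left 663 circRNAs, which held 57.9% of the junction reads. P-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. Log2 fold changes are adult minus calf and standard errors (SE) were taken from the quasi-likelihood F statistic. Group means and standard deviations (SD) are given as CPM of all junction reads of a library. The same test was run on junction reads summed per host gene over circRNAs annotated to that gene alone, which left out 142 circRNAs annotated to 2 or more genes and 1982 with no annotated gene, and tested 719 host genes. For a circRNA at 0 in every library of an age, the fold is the mean of the other age over a floor of 3 counts per library (63.4 to 84.2 CPM). It is a lower bound as to the age at 0 only and leaves out the spread of the other age. Floors and intervals cover counting error only, since duplicate reads cannot be told from independent molecules.

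There were 15 host gene lists. They covered adipocyte, lipid, signalling, matrix, vessel, chromatin, cell cycle and ubiquitin genes, widely described circRNA hosts, and markers of muscle, immune cells, nerve and epithelium. Lists with 5 or more tested host genes were tested with camera of limma 3.58.1 at a preset correlation of 0.01, with an estimated correlation and fry beside it. For the ratio of junction to non-junction reads, limma with a trended prior was run on log2 ratios with a pseudocount of 0.5. It covered 1070 circRNAs detected in all libraries with a mean of at least 10 non-junction reads, after each library was centred on its median. Measures with 1 value per library were compared by a two-sided exact permutation test over all 20 assignments, whose smallest possible p is 0.1. The comparisons of the ages, their adjusted p threshold, the 15 gene lists and the rule for naming were fixed before the data were examined; fits and tests of explanations chosen later are said to be so. For the ratio, the use of non-junction reads, the filter, the pseudocount and the centring were set once the files were seen. The text names the 10 circRNAs that passed in each direction with the smallest p and 1 direction in all 9 adult-calf pairs of libraries. It also names up to 3 per list that passed, the 10 most abundant circRNAs, the 3 host genes of each list with the smallest p, and the 3 largest folds each way in the authors' deposited table. This gave 42 circRNAs and 32 host genes, of which those with the clearest results are described; names outside it are said to be chosen after their values were seen.

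Alternatives were size factors of DESeq2 1.42.0 inside edgeR, total counts, the DESeq2 Wald test, limma-voom, no filter, a mean of at least 10 counts, an adjusted p of 10%, a replicate block, other pseudocounts, other detection limits, and each library left out in turn. After the data were seen, fits were added without calf 3 and adult 3 together, without circRNAs of 2 or more genes, without circRNAs at 0 in 1 age, and with the lipid lists pooled. Scaling to mapped reads was not run, since mapped totals were not used here, and microRNA site predictions were not analysed here. A deposited table of circRNA lengths was left out because the annotation table holds the same lengths. Figures and tables were made with Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.

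The tests of circRNAs, host genes, the ratio and lists by camera were tried on simulated counts with the means and library sizes of these data. For circRNAs, host genes and the ratio, 200 items were changed. Items were drawn independently, with 1 common dispersion for circRNAs and 1 for host genes, and non-junction reads had counting error only. Single outlying libraries, as at HSPA1A, were therefore not simulated. For circRNAs, edgeR recovered 98.4% of tested 4-fold changes, 21.7% of 2-fold changes and 1.7% of 1.5-fold changes among 654 tested circRNAs. It called 80, of which 5 were unchanged, and 0 had the wrong sign. For host genes it recovered 96.9%, 32.3% and 8.8% among 726 tested, with 2 unchanged of 89 called. The ratio test recovered 53% of 4-fold and 4.5% of 2-fold changes among 1070 circRNAs, with 1 unchanged of 39 called. With the chromatin list lowered 2-fold in simulation, camera gave an adjusted p of 7.7e-08 and called 0 of the other lists among 8 tested.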

Results

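CircRNAs of subcutaneous fat were compared between 3 Qinchuan calves of 6 months and 3 adults of 24 months, to find which back-spliced RNAs differ between these ages. The calf libraries held 37218, 39573 and 35616 junction reads and the adult libraries 37946, 47298 and 39970. Over the 6 libraries, 14274 circRNAs had 237621 junction reads. Of these circRNAs, 1192 were read in all 6 libraries and held 63.4% of the reads, while 8454 (59.2%) were read in 1 library only. UTRN, which codes for the membrane-cytoskeleton linker utrophin, gave 55 circRNAs, the most of any gene. PREX2, a regulator of Rac signalling, gave 31 and SYNE1, which codes for a nuclear envelope spectrin repeat protein, gave 30. The fatty acid transporter gene CD36 gave 20. By the deposited classes, 7744 circRNAs (54.3%) spanned exons and introns, 3448 were intronic, 1982 had no annotated gene and 1100 were exonic only.

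Adult libraries had 5157 ± 386 circRNAs (SD, n = 3) and calf libraries 4669 ± 219 (SD, n = 3), a difference of 487 (two-sided exact permutation p = 0.1, the smallest this design allows). After thinning to the smallest library the difference was 76.4 (exact permutation p = 0.3). Exonic circRNAs held 12.1 ± 0.492% of adult reads and 10.9 ± 3.04% of calf reads (SD, n = 3 per age, exact permutation p = 0.4). The calf spread came from calf 3, with 14.4% against 9.11% and 9.22% in calves 1 and 2. There the exonic circRNA of HSPA1A, described below, alone held 4.44% of reads, against 1.40% in adult 3. In the other libraries this circRNA held 0.18% to 0.72% of reads. The exonic share without it was not tested, so the permutation p of 0.4 does not show that the remaining exonic share was alike. Among the 23 such measures the smallest Benjamini-Hochberg adjusted p was 0.657.

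The most abundant circRNA of the tissue, novel_circ_0000201, came from the chromosome 10 locus of PNP, the purine nucleoside phosphorylase gene, and the unnamed gene ENSBTAG00000037452 (26671776 to 26681924). It took 3.06% of junction reads on average. A further circRNA of this locus took 1.56%. Both are annotated to 2 genes, so the assignment of their reads to 1 gene is uncertain. The BTNL9 circRNA, from a butyrophilin-like gene on chromosome 7, stood at 14384 ± 4874 CPM in calves and 15501 ± 2643 CPM in adults (SD, n = 3 per age). The circRNA of HSPA1A, an inducible heat-shock protein gene on chromosome 23, spans 18654 bases with a spliced length of 1926. Whether its reads come from 1 copy of the gene was not tested. It had 269, 219 and 1580 reads in calves 1 to 3 and 69, 105 and 560 in adults 1 to 3. Its log2 change of -1.54 ± 0.84 (SE) did not pass (edgeR adjusted p = 0.234), and it depended on calf 3 and adult 3. It was -0.07 without calf 3 (adjusted p = 0.952), -3.06 without adult 3 (0.0381) and -1.57 without both, a fit added after the data were seen (0.00576). Without a filter it passed (-1.61, adjusted p = 9e-10). The PNP, BTNL9, MORC3, ANKS3, SERPINB1 and ATP6AP2 circRNAs among the 10 most abundant did not pass either, with adjusted p from 0.0527 for SERPINB1 to 0.734 for BTNL9. The PNP circRNA novel_circ_0000201 (log2 change 0.80 ± 0.30 SE, adjusted p = 0.0832) passed without adult 3 (0.0152), with DESeq2 (0.00989), with limma-voom (0.0389) and without a filter (0.00518). SERPINB1 passed with DESeq2 (0.0201), limma-voom (0.0317) and total counts (0.0477).

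**Figure D1:**
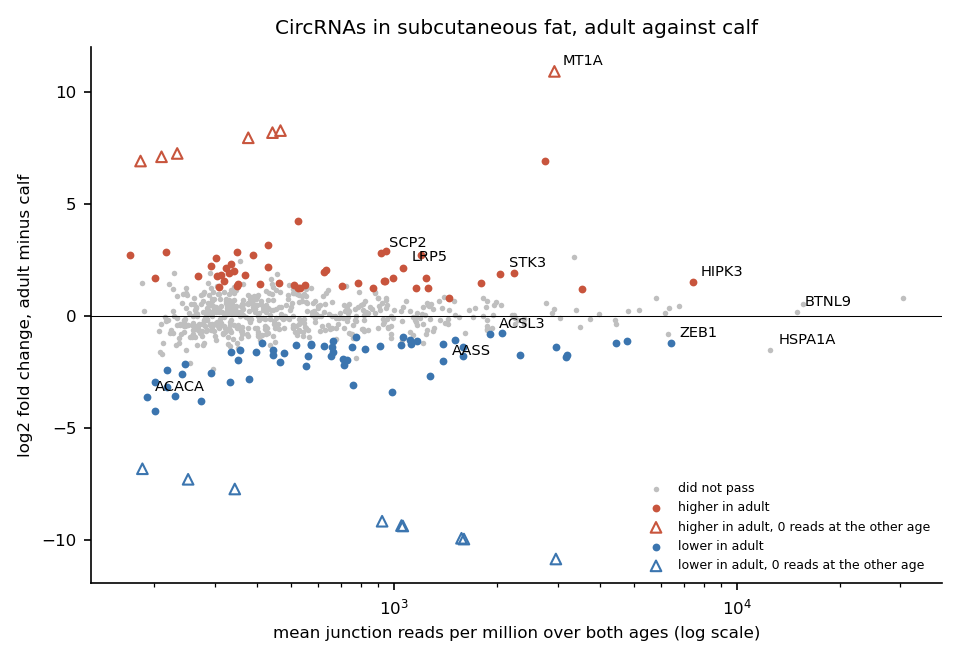
Each point is 1 of the 663 tested circRNAs, placed by its mean CPM over both ages (log scale) and its log2 fold change, adult minus calf. Of these, 57 were higher and 69 lower in adult fat; triangles mark the 16 with 0 reads at the other age, whose fitted fold depends on the software's prior count.

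Adult fat had more of the circRNAs of HIPK3, STK3, SCP2 and SAMD4A and less of those of ZEB1, AASS and CTNNAL1. The exonic circRNA of HIPK3, a homeodomain-interacting protein kinase gene and a widely described circRNA host (novel_circ_0003119, chromosome 15, 64704076 to 64705175), rose from 4061 ± 754 to 10807 ± 3002 CPM (SD, n = 3 per age). Its log2 change was 1.5 ± 0.28 (SE; edgeR adjusted p = 0.00468). An intronic circRNA of ZEB1, a zinc-finger transcription factor gene (novel_circ_0002062, chromosome 13, 34195149 to 34208869), fell from 9164 ± 979 to 3684 ± 366 CPM (log2 change -1.23 ± 0.23 SE, adjusted p = 0.00468). The circRNA of STK3, a kinase of the Hippo pathway (novel_circ_0002653, chromosome 14, 67763757 to 67764595), rose from 909 ± 172 to 3179 ± 748 CPM (log2 change 1.89 ± 0.27 SE, adjusted p = 0.000845). The circRNA of SCP2, a sterol carrier protein gene (novel_circ_0010175, chromosome 3, 93912588 to 93936812), rose from 244 ± 128 to 1590 ± 580 CPM (log2 change 2.79 ± 0.44 SE).

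The circRNA of AASS, whose enzyme starts lysine breakdown (novel_circ_0010690, chromosome 4, 87352683 to 87371198), fell from 2253 ± 459 to 533 ± 129 CPM (SD, n = 3 per age). Its log2 change was -2.01 ± 0.29 (SE; edgeR adjusted p = 0.000983). The circRNA of CTNNAL1, an alpha-catenin-like gene (novel_circ_0012633, chromosome 8, 100255322 to 100261041), fell from 668 ± 33.8 to 87.9 ± 10.9 CPM (adjusted p = 0.000786; 0.0559 with limma-voom). A circRNA across CYP21A2, a steroid hydroxylase gene, and its neighbour ENSBTAG00000037533 (novel_circ_0006984, chromosome 23, 27142504 to 27185609) fell from 2226 ± 331 to 324 ± 196 CPM. It is annotated to 2 genes, so the assignment of its reads to 1 gene is uncertain. In the authors' deposited table, novel_circ_0006990 of this pair was higher in adults (log2 fold change 6.44), and the others listed for the pair were lower. That circRNA was not tested here. The circRNA of SAMD4A, which codes for an RNA-binding repressor of translation (novel_circ_0000514), rose by 1.68 ± 0.30 on the log2 scale (SE). That of IMPA2, an inositol monophosphatase gene (novel_circ_0007368), and a neighbouring gene rose by 1.91 ± 0.27.

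In all, 126 of the 663 tested circRNAs passed the edgeR test, 57 higher and 69 lower in adults. All 126 kept 1 direction in all 9 adult-calf pairs of libraries, as did 271 of the 663 (40.9%; chance gives 10%). Among the 110 that were read at both ages the median absolute log2 change was 1.72. The HIPK3, ZEB1, STK3, SCP2, AASS, CTNNAL1, CYP21A2, SAMD4A and IMPA2 circRNAs named above were among the 44 that also passed in each of the 6 fits without 1 library. The number that passed was 71 without calf 1 (36 higher, 35 lower), 74 without calf 2 (34 and 40), 82 without adult 1 (37 and 45) and 81 without adult 2 (37 and 44). It rose above 126 without library 3 of either age, to 131 without calf 3 and 138 without adult 3. Without a filter on low counts it was 202, and DESeq2 called 37 as higher.

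A set of 16 circRNAs passed with 0 reads in every library of 1 age, 7 read in adults only and 9 in calves only. The circRNA of MT1A, a gene for a metal-binding metallothionein (novel_circ_0004167, chromosome 18, 24060144 to 24106951, exonic), had 215, 373 and 163 reads in adults and 0 in calves, at least 73.3-fold higher (edgeR adjusted p = 1.08e-05). Next to it, a circRNA across a pair of genes both named MT1E (novel_circ_0004172, 24108423 to 24118093) rose from 44.8 ± 77.6 to 5454 ± 1453 CPM (SD, n = 3 per age; log2 change 6.92, and 10.8 without calf 1, the only calf with reads). The peptide transporter gene TAP2 in the major histocompatibility region of chromosome 23 gave a circRNA (novel_circ_0007173) at least 11.0-fold higher in adults. Circles across ABCA9 and ABCA6, genes of the ABC transporter family on chromosome 19 (novel_circ_0004909), and across PHYH, the peroxisomal phytanoyl-CoA hydroxylase gene, and a neighbour on chromosome 13 (novel_circ_0001996) were at least 9.38-fold and 11.6-fold higher. The circle across PHYH varied among adults 1 to 3, with 38, 65 and 17 reads. An intronic circRNA of the matrix proteoglycan gene VCAN on chromosome 7 (novel_circ_0012571) was at least 5.82-fold higher.

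In the other direction, 5 circRNAs across the unnamed genes ENSBTAG00000037890 and ENSBTAG00000000229 on chromosome 3 were read in calves only. The most abundant (novel_circ_0010234, 99813339 to 99845925) had 251, 281 and 141 reads in calves, at least 81.8-fold the adult level (edgeR adjusted p = 1.08e-05). The other 4 (novel_circ_0010232, novel_circ_0010235, novel_circ_0010236 and novel_circ_0010237) were at least 25.5-fold to 44.1-fold lower in adults. A circRNA across the class I histocompatibility genes JSP.1 and BOLA on chromosome 23 (novel_circ_0007017) was at least 29.3-fold lower. The circRNA of ENSBTAG00000010166, also on chromosome 23 (novel_circ_0007004), was at least 9.47-fold lower, and that of APC, a scaffold gene that restrains Wnt signalling (novel_circ_0000064, chromosome 10), at least 5.09-fold lower. CACHD1, RPS6KC1 and ADGRE1 gave the remaining 3, named after their values were seen. Of the 16, 8 were annotated to 2 or more neighbouring genes, so the assignment of their reads to 1 copy is uncertain; the metallothionein and histocompatibility genes also have close copies.

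**Figure D2:**
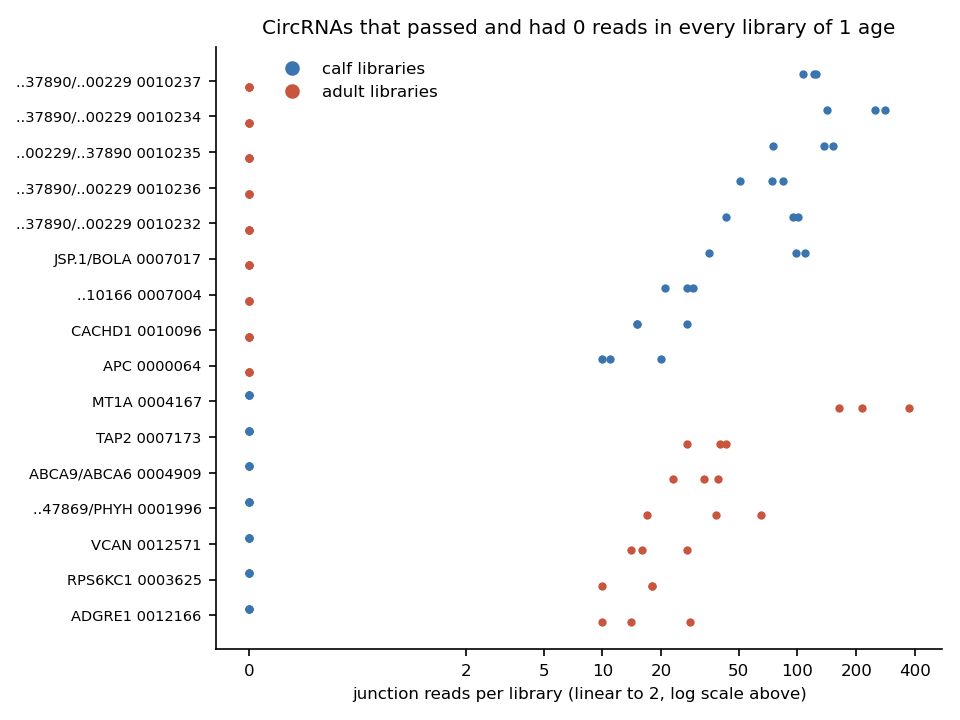
Junction reads per library (linear to 2, log scale above) of the 16 circRNAs that passed with 0 reads in every library of 1 age; each point is 1 library and the labels give the gene symbols, Ensembl identifiers shortened to their last digits, and the circRNA number. MT1A had 163 to 373 reads in adults, and novel_circ_0010234 had 141 to 281 in calves.

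Summed per host gene, the members of the 3 fixed lipid lists that passed were all lower in adult fat, while SCP2, a sterol carrier gene outside these lists, was higher (log2 change 2.33 ± 0.36 SE, edgeR adjusted p = 0.00197). Those of ACACA, whose enzyme acetyl-CoA carboxylase makes the malonyl-CoA used for fatty acid synthesis, fell from 936 ± 251 to 82.1 ± 41.5 CPM (SD, n = 3 per age; log2 change -3.44 ± 0.46 SE, edgeR adjusted p = 0.0015). Those of PPARG, the transcription factor gene that directs fat cell formation, fell from 1563 ± 477 to 655 ± 183 CPM (log2 change -1.17 ± 0.32 SE, adjusted p = 0.0278). PDE3B, a phosphodiesterase gene of insulin-controlled lipolysis, fell by 1.77 ± 0.41 on the log2 scale. PPARGC1A, a coactivator gene of mitochondrial biogenesis, fell by 3.49 ± 0.85, from 18, 15 and 24 reads in calves to 5, 0 and 0 in adults, and HADHA, a gene of mitochondrial beta-oxidation, fell by 1.32 ± 0.35. ACSL3, a long-chain acyl-CoA synthetase gene, fell by 0.82 ± 0.25 (adjusted p = 0.0493).

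By list, the adipocyte and lipid droplet genes had 4 measured members, 2 lower and 0 higher. Adjusted over the list alone, 2 were lower and 1 higher. The member higher in that count was CD36, at 1250 ± 330 CPM in calves and 2202 ± 531 CPM in adults (SD, n = 3 per age; adjusted p = 0.0535 over all host genes, 0.0379 without calf 3 and 0.0441 without adult 2). A single circRNA of CD36, novel_circ_0010459, rose from 418 ± 60.4 to 998 ± 316 CPM (adjusted p = 0.0182). It did not pass without calf 1 (0.0568), calf 2 (0.102), calf 3 (0.0653) or adult 1 (0.0795), nor with DESeq2 (0.0541) or without a filter (0.111). Fatty acid and triglyceride synthesis had 4 measured members, 2 lower, and 4 lower adjusted over the list alone, which added SCAP (log2 change -1.28 ± 0.43 SE) and PCCA (-1.14 ± 0.42 SE). Fatty acid oxidation had 2 measured members, both lower, and both lower adjusted over the list alone. Pooled after the values were seen, 6 of 10 lipid members were lower against 41 of 709 other host genes (odds ratio 24.1, 95% interval 5.48 to 121, Fisher exact p = 9.8e-06). This p is not independent of the choice to pool. Tested list by list for members that passed in either direction, 0 of the 3 were enriched after adjustment (Fisher exact p 0.077, 0.077 and 0.0152; Benjamini-Hochberg adjusted p 0.243, 0.243 and 0.167 for adipocyte, synthesis and oxidation genes).

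The ACACA call was kept in each of the 6 fits without 1 library but not with limma-voom (adjusted p = 0.0725). PDE3B did not pass without calf 2 (adjusted p = 0.0693), and PPARGC1A not without calf 2 (0.0605), calf 3 (0.0678) or adult 2 (0.065), nor with limma-voom (0.0587). The log2 change of PPARGC1A was -7.32 without adult 1, the only adult with reads, so its size is uncertain. PPARG did not pass without calf 3 (0.0905), adult 1 (0.076), adult 2 (0.0551) or adult 3 (0.061). HADHA did not pass without calf 1 (0.0911), calf 2 (0.109), adult 1 (0.0602) or adult 2 (0.0809), nor with DESeq2 (0.112), with limma-voom (0.0551) or without a filter (0.14). Of the fits without 1 library, ACSL3 passed only without adult 3 (0.0289; 0.117 without calf 1, 0.0563 without calf 2, 0.13 without calf 3, 0.176 without adult 1, 0.143 without adult 2). It did not pass with DESeq2 (0.0912), without a filter (0.074) or with a mean of at least 10 counts (0.0512). Without calf 3 and adult 3 together, a fit added after the data were seen, only ACACA of these 6 passed. Direction was kept by each of these 6 genes in each of these fits.

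**Figure D3:**
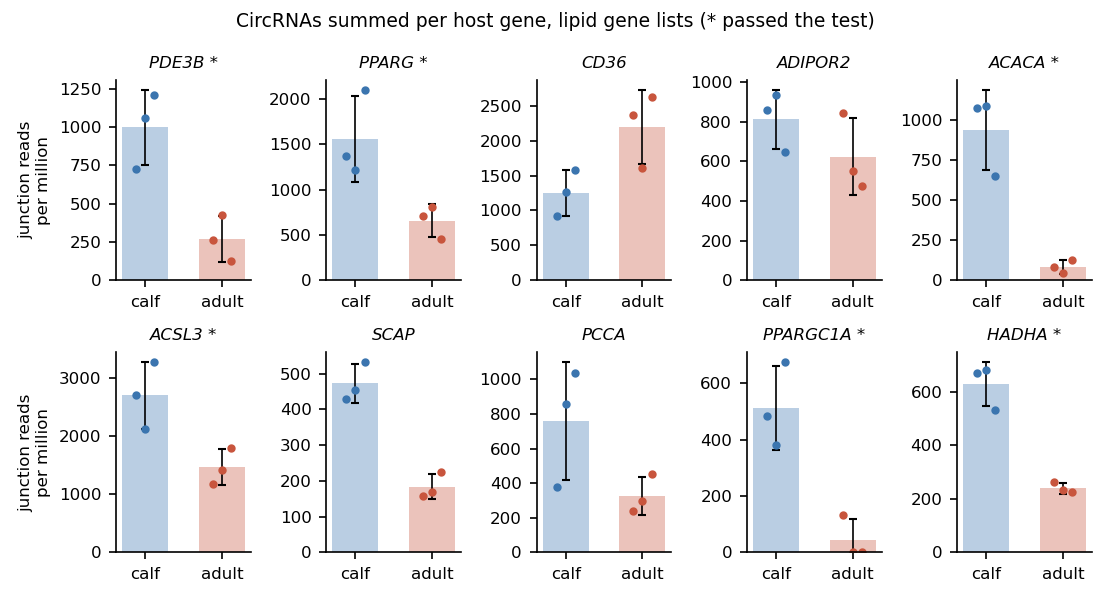
Junction reads (CPM) summed over the circRNAs of each host gene, for the 10 measured members of the lipid lists; points are libraries, bars are means and error bars are SD (n = 3 per age), with stars on the 6 genes that passed. ACACA fell from 936 to 82.1 and CD36, which did not pass, stood at 1250 in calves and 2202 in adults.

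Among signalling genes, the WNT, TGF-beta and BMP list had 9 measured members, 1 higher and 2 lower (3 higher and 2 lower adjusted over the list alone). APC fell from 862 ± 119 to 123 ± 89.2 CPM (SD, n = 3 per age; edgeR adjusted p = 0.00248), ZEB1 fell by 1.15 ± 0.21 on the log2 scale, and the Wnt co-receptor gene LRP5 rose by 1.68 ± 0.36 (0.0582 without calf 2). The insulin and mTOR list had 5 measured members, 1 higher and 1 lower, with the same counts adjusted over the list alone. TBC1D4, a regulator of insulin-driven glucose transporter traffic, fell from 1572 ± 346 to 332 ± 171 CPM (log2 change -2.17 ± 0.37 SE, adjusted p = 0.003). Among 7 matrix and fibroblast genes VCAN rose, from 17.9 ± 31 to 698 ± 294 CPM (log2 change 5.11, and 7.81 without calf 1, the only calf with reads), and 0 fell (2 higher adjusted over the list alone, with ADAMTS9). Among 4 endothelial and angiogenesis genes, HIF1A, the hypoxia-response factor gene, rose by 1.32 ± 0.32, the same count adjusted over the list alone. It did not pass without calf 1 (0.11), calf 2 (0.0889) or adult 2 (0.0677).

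Of 15 chromatin regulators 1 was higher, KAT6A (adjusted p = 0.0483), and 0 were lower; adjusted over the list alone, 0 passed. KAT6A passed in 1 of the 6 fits without 1 library (0.0456 without adult 2; 0.183 without calf 1, 0.109 without calf 2, 0.0528 without calf 3, 0.0906 without adult 1, 0.108 without adult 3), and not with DESeq2 (0.108), with limma-voom (0.0646), without a filter (0.112) or with a mean of at least 10 counts (0.0636). Of 11 ubiquitin ligase genes, HERC1 fell by 1.42 ± 0.30 (edgeR adjusted p = 0.00676) and MIB1 was higher (adjusted p = 0.0366), with the same counts adjusted over the list alone. Of the fits without 1 library, MIB1 passed only without adult 3 (0.0392). It did not pass without calf 1 (0.0678), calf 2 (0.0644), calf 3 (0.0826), adult 1 (0.131) or adult 2 (0.053), nor with DESeq2 (0.0669) or limma-voom (0.105). Among 13 widely described circRNA hosts, HIPK3 rose by 1.5 ± 0.26 (adjusted p = 0.003) and 0 were lower, also adjusted over the list alone. Of 6 cell cycle genes 0 passed, and CDK8 and CDK13 were lower adjusted over the list alone (log2 change -0.83 ± 0.27 and -0.74 ± 0.25 SE). In total 89 of 719 host genes passed, 42 higher and 47 lower, against 55 (24 higher, 31 lower) without calf 2. The number was 113 without calf 3 and 123 without adult 3.

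The 4 fixed lists of markers of other cell types had few circRNA reads. By circRNAs of 1 gene, skeletal muscle genes had 308 reads in adult 2 and at most 9 in any other library. The immune list had 7 to 15 reads per library and the nerve list 0 to 6, and the epithelium list was read in calf 3 only, with 13 reads of LAMA3. None of these 4 lists had a member that passed the filter. The immune list stood at 282 ± 81.1 CPM in adults and 298 ± 122 CPM in calves (SD, n = 3 per age, exact permutation p = 0.9). Outside the lists, and chosen after their values were seen, ADGRE1 and CD5L, genes expressed by macrophages, were higher in adults. Whether the number of macrophages differed was not tested. ADGRE1 had 2, 9 and 16 reads in calves and 44, 72 and 457 in adults (edgeR adjusted p = 0.00582; 0.0541 without calf 2 and 0.178 with limma-voom). Its log2 change was 4.30 ± 0.87 (SE) and 2.56 without adult 3. CD5L had 0, 3 and 6 reads in calves and 140, 77 and 21 in adults (adjusted p = 0.003; 0.285 with limma-voom). By camera, 0 of the 7 lists with 5 or more measured members passed (0 at an unadjusted p under 0.05, smallest p 0.164; 0 with an estimated correlation). By fry, 2 passed: cell cycle genes, lower, and widely described circRNA hosts, higher (each adjusted p = 0.00775, against 0.71 by camera). Fry asks whether the members of a list change at all, and camera whether they change more than other host genes. In either direction, fry called all 7 tested lists, so that count does not set any of them apart. Fatty acid and triglyceride synthesis had 4 measured members, too few for the test. It had 5 or 6 in some fits without 1 library and was then lower by camera. Adjusted p was 0.000332 without calf 1, 0.0485 without calf 3, 0.00225 without adult 1, 0.0285 without adult 2 and 0.00879 without adult 3. The fit without calf 2 gave this list no test. These fits share most libraries and include members that the full fit did not test, so they are not separate evidence.

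The ratio of junction to non-junction reads changed at 17 of 1070 circRNAs, 5 higher and 12 lower in adults. At STT3B, a subunit gene of the oligosaccharyltransferase (novel_circ_0006844), the ratio rose by 2.13 ± 0.43 on the log2 scale (SE, n = 3 per age; limma adjusted p = 0.00471). There, junction reads were 23 to 25 in each library and non-junction reads fell by 2.25 ± 0.28 (SE). At ADRA1A, an alpha-adrenergic receptor gene, the ratio rose by 2.79 ± 0.63 and non-junction reads fell by 2.91 ± 0.32. At a circRNA across ABCA6 and ABCA10 the ratio fell by 2.02 ± 0.41, with non-junction reads higher by 1.72 ± 0.22. The AASS and CYP21A2 circRNAs lost ratio because junction reads fell, with non-junction changes of -0.15 ± 0.28 and 0.12 ± 0.35. At SAMD4A and CTNNAL1 non-junction reads moved with junction reads, by 1.53 ± 0.28 and -2.33 ± 0.38 (SE, limma adjusted p = 0.0348 and 0.0215). Without passing, they moved by 1.05 ± 0.24 at HIPK3, 1.18 ± 0.34 at STK3 and 2.17 ± 0.89 at SCP2. The ratio did not pass at any of these circRNAs or at that of ZEB1. STT3B, ADRA1A and ABCA6 with ABCA10 were chosen here after their values were seen. The number that passed was 1 without calf 1, 1 without calf 2, 58 without calf 3, 11 without adult 1 and 2 without adult 2. Non-junction reads alone passed at 24 circRNAs, 9 higher and 15 lower. Across circRNAs, which are not independent replicates, junction and non-junction log2 changes had a Pearson r of 0.404 and a Spearman rho of 0.35. Of the 126 circRNAs that passed by junction reads, 76 were in this test. Non-junction reads passed in the same direction at 5 of them, and the ratio at 12. The ratio contains the junction reads by which these 76 were selected, so the count of 12 is no independent evidence of a change in circularisation.

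**Figure D4:**
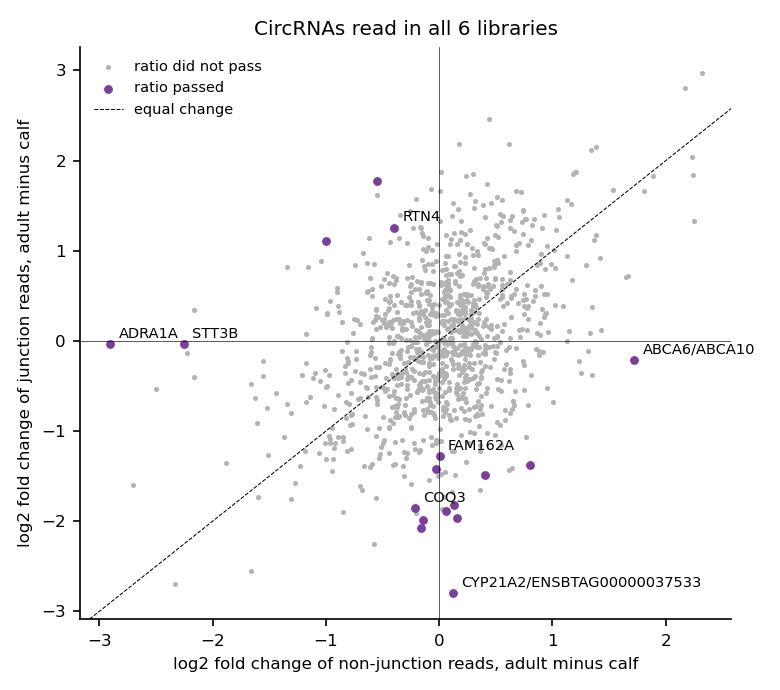
Log2 fold change, adult minus calf, of junction reads against that of non-junction reads for the 1070 circRNAs read in all 6 libraries with enough non-junction reads; the dashed line marks equal change and coloured points are the 17 whose ratio passed. STT3B and ADRA1A lie to the left, with fewer non-junction reads in adults, and ABCA6/ABCA10 to the right.

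The authors' deposited comparison lists 81 circRNAs, 33 higher and 48 lower in adults, with adjusted p up to 0.0489. In the authors' deposited table the largest folds were those of MT1A, TAP2 and the PHYH locus (higher) and of 3 circRNAs across ENSBTAG00000037890 and ENSBTAG00000000229 (lower). Of the 81 in the authors' deposited table, 56 were tested here and 55 passed in the same direction. The other 25 did not meet the filter on low counts. Without that filter all 81 passed, but this used the same counts and is no independent check. The fit without a filter called 202 circRNAs and kept 86 of the 126 that passed with it. Among its calls was HSPA1A (edgeR adjusted p = 9e-10), whose reads were high in 1 library of each age. A further 71 circRNAs passed with the filter and were not in the authors' deposited table. In the authors' deposited ontology table, 4 terms had a corrected p under 0.05 (0.0271 each), among them antigen processing and presentation with 5 of 58 host genes, all 5 on chromosome 23. Heme binding had 6 host genes in the authors' deposited ontology table, 3 of them on chromosome 3. In the authors' deposited KEGG table, vascular smooth muscle contraction had 5 host genes, arachidonic acid metabolism 4 and antigen processing 4 (corrected p = 0.0493 each).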

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

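The fits without calf 3 and adult 3 together, without circRNAs of 2 or more genes, and without circRNAs at 0 in 1 age, and the leave-one-out and replicate block fits of the ratio, were chosen after the data were seen. Of the 126 circRNAs and 89 host genes that passed, 44 and 39 passed in each fit without 1 library; over those fits the counts ran from 71 to 138 circRNAs (34 to 67 higher, 35 to 71 lower) and from 55 to 123 host genes (24 to 59 higher, 31 to 65 lower). Without a filter 202 circRNAs passed (97 higher, 105 lower), 86 of them among the 126, and the DESeq2 Wald test called 37 higher. The cause was not tested. With an adjusted p of 10%, a looser threshold, 91 circRNAs were higher and 155 host genes passed (77 higher, 78 lower). Without calf 3 and adult 3, 164 circRNAs and 122 host genes passed, 65 of the host genes higher. Without circRNAs of 2 or more genes 114 passed, and without those at 0 in 1 age 107. Size factors, total counts, limma-voom and a mean of at least 10 counts kept the counts of circRNAs and host genes within 1.5 times. Lists passing by camera ranged from 0 to 1 without 1 library, where fatty acid synthesis had enough members for a test, with 2 by fry and 7 by fry in either direction. The ratio count was 16 to 21 with other pseudocounts or only the upper part of the non-junction reads, and 1 to 58 without 1 library. The difference in detected circRNAs ranged from 276 to 654 and that in exonic share from 0.287 to 2.95 percentage points without 1 library. Of the named circRNAs and host genes, 10 to 20 no longer passed without 1 library, and only BTNL9 changed sign, from 0.177 to -0.105 without calf 3 (adjusted p = 0.811), with 0.348 without adult 3, and it passed in none. With the age means removed, same-numbered libraries had correlations of -0.05, 0.074 and 0.02. These show no clear pairing of the animals by replicate number, but 3 values cannot exclude a batch shared by number. With a replicate block 56 circRNAs (27 higher, 29 lower), 101 host genes, 1 ratio and 0 lists passed. Of the named results, 14 no longer passed with this block and 2 came to pass. These 2 were the circRNA of HSPA1A (edgeR adjusted p = 0.0197) and the more abundant PNP circRNA (0.0241). With 3 animals per age, simulated 2-fold changes were recovered for 21.7% of circRNAs, so smaller differences were mostly not detectable at this depth. Scaling to mapped reads and microRNA sites were not run, and detection at 2 reads equals the reported value.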

Other observations

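Tests of shared copies, single animals, the 4 named hosts, the fixed proportion at HSPA1A, depth and myosin copies in adult 2, and the splits of the libraries were chosen after the results were seen. Among host genes outside the fixed lists, those named in this paragraph were chosen after their values were seen, from the 39 that passed in each fit without 1 library. PANK3, a pantothenate kinase gene of coenzyme A synthesis, fell from 1424 ± 271 to 295 ± 61.8 CPM (SD, n = 3 per age; log2 change -2.19 ± 0.31 SE, edgeR adjusted p = 0.0016). COQ3, a methyltransferase gene of ubiquinone synthesis, fell by 1.45 ± 0.24 on the log2 scale, HIBCH, a gene of valine breakdown, by 1.42 ± 0.28, and ACAD10, an acyl-CoA dehydrogenase family gene, by 2.90 ± 0.53. The glutathione transferase gene GSTM2 fell by 2.02 ± 0.37 and the organic cation transporter gene SLC22A3 fell by 3.28 ± 0.54. In the other direction, SCP2 rose by 2.33 ± 0.36 and CD5L, a gene of a macrophage-secreted protein, went from 0, 3 and 6 reads in calves to 140, 77 and 21 in adults (adjusted p = 0.003). The interleukin-6 receptor gene IL6R rose by 2.32 ± 0.46, the aggrecan-cleaving protease gene ADAMTS5 by 3.46 ± 0.67 and the stress-response gene SESN1 by 1.44 ± 0.28. With limma-voom, CD5L (adjusted p = 0.285), ADAMTS5 (0.181), IL6R (0.0708), SLC22A3 (0.0606) and ACAD10 (0.0514) did not pass. Some sizes depended on 1 library. The log2 change of ADAMTS5 was 2.92 without calf 3 and 4.49 without calf 2, and that of CD5L 3.81 without adult 1 and 5.60 without calf 3. That of SLC22A3 was -2.74 without adult 1 and -4.11 without adult 2, and that of ACAD10 -2.46 without calf 1 and -3.79 without adult 2. No enrichment of the genes named in this paragraph was tested.

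CircRNAs read at 1 age only were led by the metallothionein locus in adults and the chromosome 3 locus in calves. Differences between single animals unrelated to age are argued against: with a mean of at least 10 reads, the calf and adult sets held 18 and 17 circRNAs (14 and 13 loci, with circRNAs that share a gene counted once), and the highest of the other 18 sets of 3 libraries held 2. Reads shared between neighbouring copies of a gene stay open and could account for part of it: counted by locus, because 5 of the 16 overlap at 1 locus of chromosome 3, 4 of 12 loci were annotated to 2 or more genes, against 8 of 94 loci of the other circRNAs that passed (Fisher exact p = 0.0291). The count by locus replaced a count by circRNA whose result had been seen. A host gene that was not read at the age without the circRNA is argued against for APC and TAP2. Their other circRNAs had 446 or more non-junction reads in each library of that age. At the loci of PHYH and of ABCA9 with ABCA6, other circRNAs of either gene had 872 or more and 934 or more such reads. Which of the 2 genes was read stays open there. The ABCA9 with ABCA6 values were those of a circRNA across ABCA6 and ABCA10, so ABCA9 was not shown to be read. These 4 were the only ones, of 15 with another listed circRNA, to reach 100 such reads in all 3 libraries. They were picked by that bound. For the rest, a gene that was not read cannot be told apart from a loss of the circle alone. A gene is listed only where a circRNA was read. Age stays a possible explanation, untested beyond these 6 animals. Any other difference shared by the 3 calves or by the 3 adults cannot be told apart from age in these counts.

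HSPA1A junction reads were high in calf 3 (1580) and adult 3 (560) against 69 to 269 elsewhere. Junction reads kept a nearly fixed proportion to the non-junction reads of the locus, 3.37% to 5.35%, with an SD of the log2 ratio of 0.226 against a median of 0.587 for 29 circRNAs of at least 100 reads on average, 3 of them with a smaller SD. This is consistent with a change in the whole locus, linear RNA or reads of close copies included, and not in circularisation alone. A heat-shock response of these animals cannot be told apart: the other heat-shock hosts gave a log2 ratio to the other libraries of -0.35 in calf 3 and 2.41 in adult 3, but only HSPA4 and BAG3 had a circRNA, with at most 12 reads in a library. A pattern in library 3 of both ages does not follow age.

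Skeletal muscle circRNAs stood out in adult 2, with 690 reads when circRNAs of 2 genes are counted (1.46% of its reads), 451 of them from MYH7 and 195 from NEB, against at most 9 in any other library. Greater depth is argued against, since 519.6 reads remained after scaling to the smallest library. Sharing among myosin copies is argued against as the only source: genes other than myosin heavy chains had 226 reads, against at most 9 elsewhere. For the myosin reads themselves such sharing stays open, since circRNAs of 1 gene held 308 of the 690 reads. Muscle tissue in the sample is a candidate source that cannot be told apart here: a second muscle list of 58 genes had 84.57 CPM in adult 2 and 237.2 in the highest other library, but rested on 5 genes and at most 9 reads in a library. The bound set beforehand would have counted this against muscle tissue; the requirement of at least 20 reads was added after the values were seen, because so few reads cannot show the absence of a tissue. The wording of the myosin test was also changed after its values were seen. No biological explanation by age was tested; adult 1 had 9 reads of this list and adult 3 had 0.

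The 10 splits of the 6 libraries into 3 and 3 are too few for a share under 0.05. The real split gave 126 circRNAs, 89 host genes and 17 ratios, and the highest of the other splits gave 1, 0 and 1, so 1 of the 10 splits was as large in each case.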
